A study of Homo sapiens with 83 samples.

How the data were processed

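Guide RNA cassettes were amplified from genomic DNA of LN229 cells expressing Cas9 and sequenced in 83 libraries from 8 screens. Per the labels' protocols, cells were treated when plated and again after 3, 6 and 9 days, and cell pellets were collected for DNA extraction at the end of the 12 days. The deposited table holds raw read counts per guide, and per the labels the authors used Bowtie 1.3.1 and MAGeCK (version not given) to make it, without stating which step each tool did, the guide reference or the mismatches allowed. The counts are whole numbers whose library totals differ, so no scaling had been applied. No sequences were realigned here.

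All 83 columns were matched to samples by the library names in the labels, and 0 columns were left unused or found duplicated. Groups were taken from the sample titles: the start (Time0), vehicle and each agent and dose of a screen. The vehicle was DMSO, or water in screen 8. The labels do not say which of the 4 and 6 vehicle libraries of screens 6 and 9 belong with which agent, so all of a screen were used as 1 control. One sample titled Time1 has a library name saying Time2 and was kept with Time1 by its title. Duplicates carry numbers, but nothing in the labels ties a number in one group to the same number in another, so samples were not paired in the main design.

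Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, in 1 fit per screen holding all groups of that screen. Libraries were scaled by TMM. The filter of edgeR (filterByExpr, minimum count 10) removed 0 of 2204 guides. Guides were tested with the quasi-likelihood functions glmQLFit and glmQLFTest, with 5, 5, 3, 3, 6, 4, 3 and 15 residual degrees of freedom in screens 2 to 9. Genes with at least 2 guides were tested with fry over their guides, which asks whether the guides of a gene move one way on balance and does not compare them with other genes. Benjamini-Hochberg adjustment ran over 362 genes within each comparison, and a gene was called at an adjusted p under 0.05. The effect of a gene is the mean of the log2 fold changes of its guides, with the SE over guides. Intron-targeting guides were kept out of the adjustment.

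Comparisons were each agent and dose against the vehicle of its screen (22), the highest against the lowest dose of 6 agents, the 3 compounds of screen 2 against each other, vehicle against the start in each screen, and Time1 against Time0 in screen 9. There were 16 gene lists, written before the files were opened from general knowledge of repair pathways: Fanconi anemia, homologous recombination, end joining, 53BP1-shieldin, mismatch repair, nucleotide excision repair, transcription-coupled repair, base excision and single-strand break repair, translesion synthesis, direct reversal, ATR-CHK1 checkpoint, ATM-CHK2 checkpoint, topoisomerase and DNA-protein crosslink repair, break ubiquitin signalling, RecQ helicase and joint-molecule resolution, and replication core. Each was tested for over-representation among lower and, separately, higher calls with a one-sided Fisher's exact test, adjusted over 480 tests. The overlap of calls between compounds that share vehicle libraries was set against 40 simulations of unchanged groups. These keep the vehicle values fixed, so 40 more, which draw the vehicle libraries as well, were added after the result was seen.

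Genes were named by a rule fixed before the data were examined. For each agent at its highest dose it takes up to 12 called genes with the lowest and 6 with the highest effect, up to 4 called members of each list, and genes chosen beforehand for what the agent does, whatever their result. Between compounds it takes up to 10 genes in each direction plus some chosen beforehand such as MGMT, MSH6 and PMS2, between doses up to 5 in each direction, and for vehicle against the start up to 12 lowest and 6 highest among genes called the same way in at least 6 screens. The rule gave 886 named results, of which 838 were called, and the text prints part of them. Results of some of these genes are not reported here.

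The procedure was tested on simulated data with the depth and spread of 3 comparisons and 25 changed genes per fold. With changes of −0.5 on the log2 scale it recovered 25, 22 and 23 of 25 genes for TMZ, illudin S and topotecan, with changes of −0.25 18, 11 and 20, and with changes of −2 all 25. Of 162 unchanged genes 6, 4 and 1 were called, and with no gene changed 0 of 362. The simulated counts came from the fitted model, so these rates hold only where it does. Among the 9 real intron targets fry gave an unadjusted p under 0.05 to 7 under topotecan dose 2, all higher. It did so for 5 under KL50 and 5 under MTZ, all higher, for 3 under dactinomycin dose 2, all lower, and for 0 under illudin S.

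The result was also computed with median-of-ratios scaling, no filter, counts summed per gene tested with edgeR or DESeq2 1.42.0, rank aggregation of guides (alpha 0.25, 20000 permutations), a rule asking for 2 guides past the guide test as well, all screens in 1 fit, only the 2 groups compared, replicate number as a block, pairs of vehicle libraries alone in screens 6 and 9, and leaving out each library in turn. Scaling on non-targeting guides could not be run. The table holds no non-targeting guides, so scaling on the 50 intron-targeting guides was added after the table was seen. No guide coordinates were used, and MAGeCK itself was not run. The labels give no concentrations, so doses were compared only as levels within an agent.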

Results

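The series measured how a pool of cells, each carrying a guide RNA against 1 DNA damage repair gene or regulator, changed in composition under DNA-damaging agents. The cells were LN229, an established human glioma line, made to express the nuclease Cas9. A guide that became rarer under an agent than under its vehicle marks a gene whose loss went with poorer growth or survival in that agent, and a guide that became more common marks the opposite. The counts do not show whether a gene was present or expressed in these cells. A lack of change therefore does not show that its product plays no part. The values were guide RNA read counts amplified from genomic DNA. The table held 2204 guides: 353 genes had 6 guides, 9 genes had 4, and 50 guides aimed at introns of 9 targets served as controls. There were 83 libraries from 8 screens, numbered 2 to 9 in the labels, in 39 groups. Every group had 2 libraries except the vehicle groups of screen 6 (4 libraries) and screen 9 (6 libraries) and the start of screen 8 (1 library). Cells were treated when plated and again on days 3, 6 and 9, and were collected on day 12. Doses were given only as level numbers. Values at lower doses are given for genes chosen after the values were seen.

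Total reads per library ran from 723716 (start of screen 2, replicate 1) to 16149865 (vehicle of screen 9, replicate 5), with a median of 6883914. The lowest and highest totals were 723716 and 6015496 in screen 2, 3242204 and 6704090 in screen 3, 7565550 and 10521075 in screen 4, 3325340 and 12229653 in screen 5, 5137521 and 12552981 in screen 6, 5115510 and 7811073 in screen 7, 2593614 and 10358297 in screen 8, and 5596805 and 16149865 in screen 9. The median count per guide lay between 331 and 7431.5 reads, and 9 guide counts were 0 over all libraries. Values below are mean log2 fold changes over the guides of a gene against the vehicle of the same screen, ± the SE over those guides (6 guides unless 4 are named), with 2 treated libraries per group. A gene was called at an adjusted p under 0.05 over 362 genes. The gene test asks whether the guides of a gene moved one way on balance. The labels speak of duplicates without saying whether these were separate cultures, so the p-values measure a spread between samples that may be technical. A higher call is a gain relative to the other guides of the library. When libraries were scaled on the intron-targeting guides instead, the median of all genes shifted by −0.10 to −0.19 in those drug comparisons where it moved by over 0.1, and by −0.33 to −0.39 for vehicle against the start. In most comparisons fewer genes were then called higher, while more were under illudin S and under dose 2 of bleomycin and of dactinomycin, against vehicle and against dose 1.

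Loss of core replication genes, among others, depleted cells even without drug, the background against which the agents were read. The lowest means over the 8 screens for vehicle against the start were those of PPP4C, a phosphatase subunit (−2.96 ± 0.24, SD over 8 screens), UBA3, part of the NEDD8-activating enzyme (−2.93 ± 0.15), TOP2A, the topoisomerase that untangles replicated DNA (−2.74 ± 0.26), POLR2L, an RNA polymerase subunit (−2.69 ± 0.35), and RFC3, part of the clamp loader (−2.58 ± 0.20). The next were YRDC (−2.56), UBE2M (−2.53), TELO2 (−2.44), RPL9 (−2.43), HSPA9 (−2.40), the helicase gene ERCC2 (−2.39) and the sliding clamp gene PCNA (−2.35). Guides against CUL5 (0.92 ± 0.09), the cell cycle inhibitor genes CDKN2B (0.68 ± 0.05) and CDKN2A (0.63 ± 0.08) and the glycosylase gene MPG (0.54 ± 0.08) were higher. Intron-targeting guides rose too (medians of 0.27 to 0.37), so a rise here does not by itself show that loss of a gene helped growth. In at least 6 screens, 141 genes were lower and 128 higher, and in all 8 screens 106 and 78. Without screen 8, whose start had 1 library, 140 genes were lower and 126 higher in at least 6 of 7 screens, and 126 and 109 in all 7. Of the 16 replication core genes, 14 were lower in at least 6 screens, as were 9 of the 13 ATR-CHK1 checkpoint genes, while 7 of the 8 mismatch repair genes and 4 of the 4 direct reversal genes were higher, of which 0 stayed higher in at least 6 screens under the intron-guide scaling (list means of 0.27 and 0.38 became −0.10 and 0.01).

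Counts of genes lower and higher in vehicle against the start were 150 and 149 in screen 2, 145 and 131 in screen 3, 146 and 132 in screen 4, 151 and 138 in screen 5, 161 and 153 in screen 6, 150 and 146 in screen 7, 119 and 93 in screen 8, and 153 and 151 in screen 9. Under the intron-guide scaling the splits were 234 and 16, 231 and 14, 215 and 16, 227 and 11, 255 and 27, 248 and 11, 174 and 8, and 246 and 20, in the same order of screens, so that the depleted side grew and few higher genes were left. The intron guides themselves had a median of 0.27 to 0.37 in these comparisons. In screen 4 the count of 278 became 172 without start replicate 1 and 148 without start replicate 2. In screen 5 the count of 289 became 187 and 186 without start replicates 1 and 2. In screen 8 the count of 212 became 0 without either vehicle library (1 start library, and the lone vehicle sample assumed to vary like the other groups). A further group of screen 9, named Time1 and with no day given, held 0 genes called against Time0 by edgeR and fry, with 10 genes at an unadjusted p under 0.05. DESeq2 and edgeR on counts summed per gene called 0 as well, and rank aggregation of guides called 3. One library of this Time1 group carries Time2 in its library name.

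Under TMZ (temozolomide, a DNA-methylating agent), loss of mismatch repair genes gave a strong advantage and loss of Fanconi anemia genes a strong disadvantage. Guides rose against MSH6 (1.79 ± 0.06), which recognises mispaired bases, PMS2 (1.36 ± 0.17), which nicks the strand to be repaired, and PMS1 (0.65 ± 0.06). FAN1, a nuclease that acts on crosslinks, rose by 0.78 ± 0.06. FANCA (−2.16 ± 0.18), FAAP100 (−1.80 ± 0.15), FANCL (−1.73 ± 0.37), FANCF (−1.66 ± 0.16) and FANCB (−1.62 ± 0.20), all parts of the core complex that ubiquitinates FANCD2 and FANCI, fell. LIG1, the ligase that seals Okazaki fragments, fell by 1.66 ± 0.39, and so did its partner in that step, FEN1 (−0.86 ± 0.11).

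Of the 23 Fanconi anemia genes, 18 fell under TMZ, 1 (FAN1) rose and 4 were not called, BRIP1 among these (−0.04). Of the 26 homologous recombination genes, 17 fell, among them MCM9 (−1.53 ± 0.33), HROB (−1.44 ± 0.21), MCM8 (−1.14 ± 0.34) and XRCC3 (−0.95 ± 0.22), the first 3 of which act together in DNA synthesis during recombination. In mismatch repair 6 of 8 rose, and EXO1 (0.07 ± 0.17) was not called. The ubiquitin ligase gene RAD18 (−1.13 ± 0.18), the end-joining polymerase gene POLQ (−0.87 ± 0.13) and the kinase genes ATM (−0.86 ± 0.13) and PRKDC (−0.66 ± 0.11) fell. MGMT, which removes methyl groups from guanine, had 0.07 ± 0.03 and ALKBH2 0.09 ± 0.06, neither called. The glycosylase gene MPG was called at 0.13 ± 0.04, a call that ended under the intron-guide scaling and without any 1 of the 4 libraries (0.10 to 0.15). In all, 78 genes fell and 51 rose. Under the intron-guide scaling 97 were lower and 19 higher, the latter including MSH6, PMS2, PMS1 and FAN1.

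Lists were tested with a one-sided Fisher's exact test, in a family of 480 tests (16 lists, both directions, 15 agents at the highest dose). It counts genes as independent draws, so its p-values do not measure a spread between samples. By this exact test, under TMZ the lower calls held more Fanconi anemia genes (adjusted p = 1.09e-07) and homologous recombination genes (adjusted p = 1.85e-05) than other genes, and the higher calls more mismatch repair genes (adjusted p = 0.00265). Adjusted over the list alone, 20, 19 and 6 genes passed in these lists in those directions.

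MTZ and KL50, the other agents of screen 2, gave profiles in which loss of nearly every Fanconi anemia gene was a disadvantage, and in which 0 (MTZ) and 1 (KL50) of the 8 mismatch repair genes were called higher. Neither name is expanded in the labels. Under MTZ the lowest values were those of FAAP24 (−2.33 ± 0.33), the helicase gene BRIP1 (−2.23 ± 0.49), FANCI (−2.19 ± 0.27) and CENPS (−2.09 ± 0.12). Under KL50 they were those of BRIP1 (−2.35 ± 0.43), FANCA (−2.30 ± 0.33), FANCG (−2.22 ± 0.63) and UBE2T (−2.17 ± 0.57), the ubiquitin-conjugating enzyme of the pathway. Of the 23 Fanconi anemia genes 21 fell under MTZ and 23 under KL50. Of the 26 homologous recombination genes 15 and 14 fell, such as XRCC3 (−1.42 ± 0.39 and −1.31 ± 0.36), RAD51D (−1.25 ± 0.12 and −1.10 ± 0.19), RAD51B (−1.25 ± 0.19 and −1.11 ± 0.26) and BRCA2 (−0.36 ± 0.13 and −0.29 ± 0.09) under MTZ and KL50. MAD2L2, a subunit of translesion polymerase zeta, fell by 1.12 ± 0.20 and 1.17 ± 0.19, and ERCC1, a subunit of a structure-specific nuclease, by 1.42 ± 0.47 and 1.34 ± 0.45.

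Of the 8 mismatch repair genes 4 were lower under KL50, such as EXO1 (−0.60 ± 0.18) and MSH6 (−0.51 ± 0.17), 1 was higher and 3 were not called, PMS2 among these (−0.19 ± 0.11). The list test for lower calls did not pass (Fisher's exact test, adjusted p = 0.387). Under MTZ no member of that list was called by edgeR and fry: MSH6 had 0.06 ± 0.03 and PMS2 0.12 ± 0.03. MGMT was not called under MTZ (0.02 ± 0.05) or KL50 (0.07 ± 0.08), nor was ALKBH2 (0.13 ± 0.04 and 0.10 ± 0.02). Base excision and single-strand break repair genes were higher under KL50 in 9 of 23 cases, such as PARP1 (0.28 ± 0.08), but under the intron-guide scaling 0 were higher and 2 lower, and the mean of the list went from 0.11 to 0.003.

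KL50 had 70 genes lower and 42 higher, and MTZ 59 and 29. Under the intron-guide scaling KL50 had 91 lower and 2 higher, RAD23B among these, and MTZ 90 lower and 4 higher, with CHEK2, EXO5 and COPS8 among these. Median-of-ratios scaling gave 58 lower and 47 higher for MTZ. Without vehicle replicate 1 the KL50 count of 112 became 74. Among lower calls, Fanconi anemia genes (Fisher's exact test, adjusted p = 6.41e-16 for KL50 and 2.86e-14 for MTZ) and homologous recombination genes (0.000958 and 1.76e-05) were over-represented. Adjusted over the list alone, 23 and 23 Fanconi anemia genes and 17 and 16 recombination genes were lower under KL50 and MTZ. The higher base excision calls under KL50 had an adjusted p of 0.00702, with 10 adjusted over the list alone.

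The 3 compounds of screen 2 were also compared directly. Their doses are not given, so it is unknown whether they were matched. Against TMZ, KL50 was lower for MSH6 (−2.30, 95% interval over guides −2.77 to −1.83), PMS2 (−1.55), FAN1 (−1.06 ± 0.10) and BRIP1 (−2.31 ± 0.39), and for the Fanconi-associated genes CENPS (−1.37 ± 0.15) and RFWD3 (−1.09 ± 0.38) and the polymerase subunit gene MAD2L2 (−1.18 ± 0.16). It was higher for LIG1 (1.74 ± 0.40), FEN1 (0.79 ± 0.12), the deubiquitinase gene USP7 (0.79 ± 0.09), RAD18 (0.75 ± 0.09), HROB (0.74 ± 0.10) and ATM (0.50 ± 0.11). MTZ differed from TMZ in many of the same genes: BRIP1 (−2.18 ± 0.46), MSH6 (−1.73), CENPS (−1.46 ± 0.06) and FAN1 (−1.02 ± 0.04) were lower, and LIG1 (1.77 ± 0.42), FEN1 (0.92 ± 0.09), HROB (0.83 ± 0.14), RAD18 (0.83 ± 0.11) and ATM (0.77 ± 0.12) were higher.

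KL50 and MTZ differed in 3 genes, among them MSH6, which was lower under KL50 (−0.57, interval −0.96 to −0.18). PMS2 was not called (−0.31, −0.53 to −0.10, adjusted p = 0.199). These intervals take the guides of a gene as replicates and not the 2 libraries per compound, so they do not bound the difference between compounds. Nor do they show that the compounds act alike. Other genes had FANCA −0.26 (−0.56 to 0.04), FANCD2 −0.06 (−0.43 to 0.30), BRIP1 −0.12 (−0.82 to 0.57) and MGMT 0.05 (−0.12 to 0.23). The mean difference over the 23 Fanconi anemia genes was −0.02 (SD 0.17, 0 called), against −0.43 (SD 0.59, 8 lower and 1 higher) for KL50 minus TMZ and −0.41 (SD 0.62, 7 lower and 2 higher) for MTZ minus TMZ. MGMT did not differ by this test between KL50 and TMZ (0.002, −0.17 to 0.17) or MTZ and TMZ (−0.05, −0.19 to 0.09). Expression of MGMT in these cells was not measured, so these values do not show whether active MGMT sets the compounds apart.

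Of all genes, 36 were lower and 34 higher under KL50 than under TMZ, 37 and 31 under MTZ than under TMZ, and 3 and 0 under KL50 than under MTZ (31 and 24, 35 and 25, and 3 and 0 under the intron-guide scaling). The KL50 against TMZ count of 70 became 37 and 46 without KL50 replicates 1 and 2, and 46 and 32 without TMZ replicates 1 and 2. The MTZ against TMZ count of 68 became 42 and 36 without MTZ replicates 1 and 2, and 40 and 32 without TMZ replicates 1 and 2. The KL50 against MTZ count of 3 became 5 without KL50 replicate 1 and 0 without KL50 replicate 2, where MSH6 had −0.53. The lower genes shared by TMZ and KL50 numbered 51, those shared by TMZ and MTZ 50, and those shared by KL50 and MTZ 52, where 15.1, 12.7 and 11.4 come from n1 × n2 / N. Higher genes were shared in 23, 15 and 21 cases, against 5.92, 4.09 and 3.36. In 40 simulations of unchanged groups in which the shared vehicle libraries were drawn anew as well, at most 1 gene was shared in either direction by any pair. With no gene changed the procedure called 0 of 362 genes on simulated data, so that count was bound to be low. It cannot show how far shared controls raise the overlap between groups with changed genes, and neither can n1 × n2 / N. Simulations that redraw only the treated groups cannot show it either, since the vehicle values stay fixed. In all 3 compounds 44 genes were lower and 13 higher. Across genes, which are not independent replicates, r was 0.96 between KL50 and MTZ, 0.72 between TMZ and MTZ and 0.67 between TMZ and KL50. Shared vehicle libraries raise r by themselves: with no gene changed its mean over the simulations was 0.48, 0.48 and 0.49, and its highest value 0.59, 0.61 and 0.59, in the same order. The covariance across genes, which also counts the size of the effects, was 0.20, 0.15 and 0.14 in that order. With no gene changed it reached at most 0.0052, 0.0054 and 0.0048, so shared vehicle spread of the simulated size makes up little of it.

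**Figure D1:**
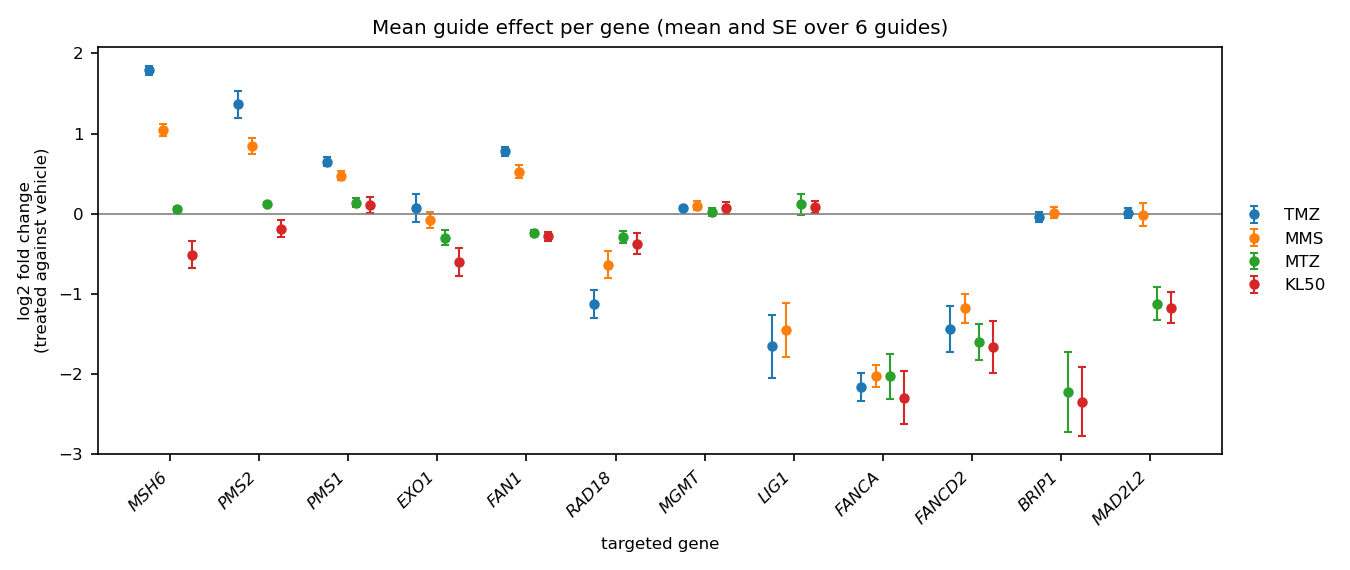
Mean guide log2 fold change against vehicle (y axis) for 12 genes (x axis) under TMZ, MMS, MTZ and KL50, where points are means and bars the SE over 6 guides. MSH6, at 1.79 under TMZ and 1.05 under MMS, had 0.06 under MTZ and −0.51 under KL50, while FANCA lay between −2.30 and −2.03 in all 4.

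MMS (methyl methanesulfonate, another methylating agent, in screen 9) also favoured loss of mismatch repair genes. MSH6 (1.05 ± 0.07), PMS2 (0.85 ± 0.10) and PMS1 (0.47 ± 0.05) rose, as did FAN1 (0.53 ± 0.08). FANCA (−2.03 ± 0.14), FAAP100 (−1.72 ± 0.12), FANCG (−1.63 ± 0.39), FANCB (−1.53 ± 0.26) and LIG1 (−1.45 ± 0.34) fell. Of the Fanconi anemia genes 19 of 23 fell and 1 rose, of the recombination genes 13 of 26 fell, with MCM9 at −0.93 ± 0.21 and HROB at −0.76 ± 0.07, and of mismatch repair 6 of 8 rose. RHNO1 (−0.98 ± 0.25), of the ATR activation machinery, ATM (−0.93 ± 0.09), PRKDC (−0.76 ± 0.14) and RAD18 (−0.64 ± 0.17) fell too. Of the 23 base excision and single-strand break repair genes 1 was lower and 6 were higher (3 and 0 under the intron-guide scaling), and 16 were not called, with POLB at 0.05 ± 0.05, XRCC1 at −0.08 ± 0.05, LIG3 at 0.06 ± 0.06 and PARP1 at 0.09 ± 0.05, and the dealkylation genes ALKBH2 (0.02 ± 0.08) and ALKBH3 (0.12 ± 0.06) were not called either.

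Under MMS 59 genes were lower and 60 higher, and 93 and 15 under the intron-guide scaling, where MSH6, PMS2, PMS1 and FAN1 stayed higher. The list tests gave adjusted p = 2.95e-11 (Fisher's exact test) for Fanconi anemia (lower), 0.000729 for homologous recombination (lower) and 0.00653 for mismatch repair (higher), with 21, 14 and 6 genes adjusted over the list alone.

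SJG-136, a code name in the labels, was run at 3 dose levels in screen 3. At dose 3 the lowest values were those of BRIP1 (−3.31 ± 0.32), WRNIP1, an ATPase that binds the Werner helicase (−2.81 ± 0.42), MCM9 (−2.74 ± 0.49) and POLQ (−2.46 ± 0.26), and FANCA (−2.29 ± 0.47), FAAP100 (−2.26 ± 0.22) and DDX11, a helicase of sister chromatid cohesion (−2.04 ± 0.23) were also low. Of the 23 Fanconi anemia genes 23 fell, and of the 26 recombination genes 18 fell, such as RAD51B (−1.95 ± 0.39), HROB (−1.90 ± 0.29) and MCM8 (−1.77 ± 0.45). In break ubiquitin signalling 7 of 9 fell, with RNF168, a ligase that marks chromatin at breaks, at −1.73 ± 0.46 and ABRAXAS1 at −0.48 ± 0.12. The deubiquitinase pair USP1 (−1.59 ± 0.14) and WDR48 (−1.84 ± 0.48) fell. ETAA1 (0.81 ± 0.03), an activator of ATR, CUL3 (0.78 ± 0.10), CAND1 (0.75 ± 0.07) and POLK (0.72 ± 0.09) rose, as did MAD2L2 (0.65 ± 0.14), which fell under KL50 and MTZ. The excision repair genes XPA (−0.03 ± 0.08), XPC (0.04 ± 0.06) and ERCC6 (0.11 ± 0.07) were not called, nor was RAD18 (−0.29 ± 0.16), while the nuclease genes ERCC1 (−1.21 ± 0.47) and ERCC4 (−0.86 ± 0.50) fell.

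At dose 3 of SJG-136 87 genes were lower and 47 higher (108 and 23 under the intron-guide scaling), at dose 2 29 and 7 (37 and 0), and at dose 1 0 and 0 by edgeR and fry. At dose 1, 29 genes had an unadjusted p under 0.05, and on counts summed per gene DESeq2 called 2 and edgeR 3, while rank aggregation called 1. The dose 2 count of 36 became 15 and 14 without vehicle replicates 1 and 2, and 4 and 18 without dose 2 replicates 1 and 2. BRIP1 had −0.64 ± 0.15 at dose 1, not called, and −2.14 ± 0.40 at dose 2. Dose 3 against dose 1 had 86 genes lower and 40 higher (102 and 24 under the intron-guide scaling), with BRIP1 (−2.67 ± 0.21), MCM9 (−2.67 ± 0.46) and WRNIP1 (−2.64 ± 0.43) lowest and CUL3 (0.79 ± 0.11) among the higher. At dose 3 the lists gave, by Fisher's exact test, adjusted p = 5.75e-14 for Fanconi anemia, 1.63e-05 for homologous recombination and 0.0133 for break ubiquitin signalling, with 23, 19 and 8 lower genes adjusted over the list alone.

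Chlorambucil, a nitrogen mustard that crosslinks DNA strands, was run in screen 4. BRIP1 (−2.99 ± 0.70), FAAP24 (−2.79 ± 0.44), DDX11 (−2.64 ± 0.42), FANCA (−2.37 ± 0.37), CENPS (−2.37 ± 0.18) and MCM9 (−2.28 ± 0.51) were among the genes that fell most. All 23 Fanconi anemia genes and 20 of 26 recombination genes fell, with RAD51D at −1.55 ± 0.21 and RAD51B at −1.78 ± 0.42. SLX4, a scaffold of nucleases (−2.05 ± 0.57), and the nuclease genes MUS81 (−0.98 ± 0.34) and EXO1 (−0.99 ± 0.27) fell, as did RMI1, a partner of the BLM helicase (−1.05 ± 0.31), and USP1 (−0.74 ± 0.09). CUL3, a scaffold of ubiquitin ligases, rose by 0.65 ± 0.04. RAD18 (−0.22 ± 0.11) and REV1 (−0.15 ± 0.08) were not called. In direct reversal 3 of 4 were called higher, but none was under the intron-guide scaling, which took MGMT from 0.25 to 0.11 and turned ALKBH2 from 0.13 to −0.01.

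Of all genes 82 fell and 31 rose under chlorambucil, with 107 lower and 4 higher under the intron-guide scaling and 79 and 56 under median-of-ratios scaling. The count of 113 became 57 and 63 without vehicle replicates 1 and 2, and 52 and 57 without chlorambucil replicates 1 and 2. Lists over-represented by Fisher's exact test had adjusted p = 2.37e-14 for Fanconi anemia (lower), 6.07e-08 for homologous recombination (lower) and 0.0305 for direct reversal (higher), with 23, 21 and 3 genes adjusted over the list alone.

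Mitomycin C, a crosslinking antibiotic, was run in screen 7 at the levels named dose 2 and dose 3. At dose 3 FAAP24 (−2.90 ± 0.50), CENPS (−2.83 ± 0.18), DDX11 (−2.77 ± 0.42), UBE2T (−2.70 ± 0.74), FAAP100 (−2.64 ± 0.44), FANCA (−2.52 ± 0.39) and BRIP1 (−2.49 ± 0.44) fell most. All 23 Fanconi anemia genes and 23 of 26 recombination genes fell, with 1 of the latter higher. The annealing helicase gene SMARCAL1 (−1.89 ± 0.33), the BRCA1 partner gene BARD1 (−1.58 ± 0.32), MAD2L2 (−1.53 ± 0.29) and MUS81 (−1.12 ± 0.23) fell. In excision repair, 6 of 17 genes were lower and 6 higher, with ERCC1 at −1.52 ± 0.49, XPA at −0.60 ± 0.22 and ERCC2 at 0.59 ± 0.17, and in transcription-coupled repair 4 of 6 were lower, such as ELOF1 (−0.89 ± 0.21) and ERCC8 (−0.66 ± 0.14). RRM1, the large subunit of ribonucleotide reductase (0.97 ± 0.29), the chromatin remodeller gene SMARCA4 (0.63 ± 0.15) and CHEK2 (0.42 ± 0.06) rose. Mismatch repair split, with EXO1 at −0.99 ± 0.30 and PMS2 at 0.29 ± 0.06.

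At dose 3 of mitomycin C 117 genes were lower and 101 higher (148 and 25 under the intron-guide scaling), and at dose 2 56 and 26 (64 and 7). The dose 2 count of 82 became 37 and 34 without vehicle replicates 1 and 2, and 32 and 39 without dose 2 replicates 1 and 2. Dose 3 had lower values than dose 2 in 84 genes and higher values in 35 (125 and 7 under the intron-guide scaling, 80 and 73 under median-of-ratios scaling), among them DDX11 (−1.81 ± 0.29), CENPS (−1.78 ± 0.16), MCM9 (−1.51 ± 0.33) and SMARCA4 (0.50 ± 0.06). Among the lists at dose 3, Fisher's exact test gave adjusted p = 6.57e-11 for Fanconi anemia and 5.76e-08 for homologous recombination, with 23 and 24 lower genes adjusted over the list alone.

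Cisplatin, a platinum agent that forms crosslinks within and between strands, was run in screen 8 with water as its vehicle. At dose 2 FANCA (−2.81 ± 0.31), MCM9 (−2.64 ± 0.62), DDX11 (−2.62 ± 0.44), BRIP1 (−2.52 ± 0.40) and FANCF (−2.30 ± 0.40) fell, and so did excision repair genes that were not called under SJG-136: ERCC8 (−2.29 ± 0.48) and ERCC6 (−1.63 ± 0.50), which act where transcription stalls, and XPA (−2.04 ± 0.67). Whether these genes differ between the agents was not tested, since they were run in different screens. Of the 23 Fanconi anemia genes 23 fell, of the 26 recombination genes 20, such as RAD51B (−1.82 ± 0.34), of the 6 transcription-coupled repair genes 5, with UVSSA at −1.54 ± 0.41, and of the 17 excision repair genes 7. RAD18, a ligase that recruits translesion polymerases to the clamp, fell by 1.45 ± 0.18. In mismatch repair 4 of 8 rose and 1 fell, with MSH6 at 1.21 ± 0.08. PBRM1, a chromatin remodeller subunit (0.86 ± 0.10), and RFC1 (0.84 ± 0.14) rose.

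At dose 2 of cisplatin 96 genes were lower and 53 higher (118 and 16 under the intron-guide scaling, where MSH6, PBRM1 and RFC1 stayed higher). At dose 1 46 were lower and 11 higher (59 and 5), with FANCA at −1.92 ± 0.35 and MSH6 at 0.28 ± 0.05, the latter not called. These counts fell without any 1 library of the groups compared, where the lone sample is assumed to vary like the other groups. Such fits also lose residual degrees of freedom, of which screen 8 had 3, so the falls do not single out a library. The dose 2 count of 149 became 48 and 40 without vehicle replicates 1 and 2, and 75 and 72 without dose 2 replicates 1 and 2. FANCA lost its call without any 1 of these 4, though its value held (−2.91 to −2.75). BRIP1 lost its call without either vehicle library or dose 2 replicate 1 (−2.48 to −2.44), and MCM9 (−2.63 and −2.55) and MSH6 (1.21 and 1.31) without either vehicle library. The dose 1 count of 57 became 0 without either vehicle library, and 2 and 0 without dose 1 replicates 1 and 2. Dose 2 was lower than dose 1 in 40 genes and higher in 18 (63 and 12 under the intron-guide scaling), among them ERCC8 (−1.46 ± 0.30), MCM9 (−1.50 ± 0.42), MSH6 (0.93 ± 0.07) and PBRM1 (0.64 ± 0.06). That count of 58 became 6 and 4 without dose 1 replicates 1 and 2, and 1 and 2 without dose 2 replicates 1 and 2, and these 4 genes lost their calls in each case, with ERCC8 then at −1.67 to −1.31 and MSH6 at 0.84 to 1.02. For the lists at dose 2, Fisher's exact test gave adjusted p = 6.14e-13 for Fanconi anemia and 1.32e-06 for homologous recombination (23 and 22 lower genes adjusted over the list alone), and 0.0671 for transcription-coupled repair (5 adjusted over the list alone).

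**Figure D2:**
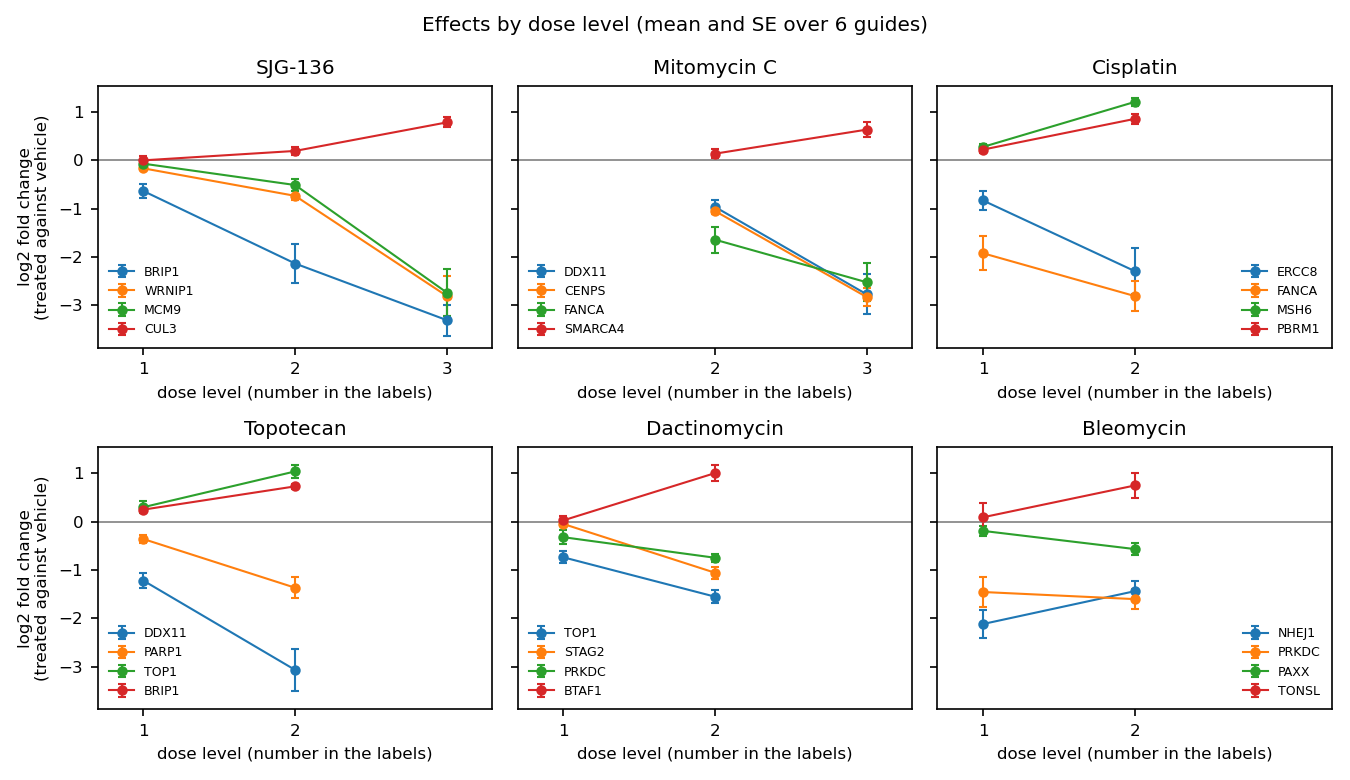
Mean guide log2 fold change against vehicle (y axis) at each dose level (x axis, the number in the labels) for 4 genes under each of 6 agents, where bars are the SE over 6 guides. BRIP1 under SJG-136 went from −0.64 at dose 1 to −2.14 and −3.31, and NHEJ1 under bleomycin from −2.12 at dose 1 to −1.44 at dose 2.

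Illudin S, a fungal toxin whose adducts block transcription, gave a narrow profile in which genes of transcription-coupled repair fell. ERCC8 (−2.67 ± 0.57), ERCC6 (−2.04 ± 0.65) and UVSSA (−1.78 ± 0.38), which handle stalled RNA polymerase, fell with STK19 (−0.38 ± 0.16), 4 of the 6 list members, while ELOF1 (−0.64 ± 0.17) was not called (adjusted p = 0.14). Of 17 excision repair genes 5 fell, namely GTF2H5, a TFIIH subunit (−2.37 ± 0.67), XPA (−1.67 ± 0.57), ERCC1 (−1.43 ± 0.47), ERCC4 (−0.75 ± 0.45) and ERCC5 (−0.73 ± 0.19). The damage sensors of the genome-wide branch were not called, with XPC at 0.04 ± 0.07 and DDB2 at 0.04 ± 0.04. Of 18 translesion synthesis genes 3 fell, namely MAD2L2 (−1.70 ± 0.33), POLK (−0.59 ± 0.12) and REV1 (−0.42 ± 0.09), too few for the list test (Fisher's exact test, adjusted p = 0.369). RFWD3 (−1.30 ± 0.39) and BLM (−0.86 ± 0.31) fell as well. Of the Fanconi anemia genes 1 of 23 fell, and no gene rose at an adjusted p under 0.05 by edgeR and fry.

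In screen 5, 17 genes fell and 0 rose under illudin S (18 and 1 under the intron-guide scaling), and 63 genes had an unadjusted p under 0.05. DESeq2 and edgeR on counts summed per gene called 77 and 29 genes in either direction. The count of 17 became 0 without vehicle replicate 1 or 2, and 3 without illudin S replicate 1 or 2, where the lone sample is assumed to vary like the other groups and the fit loses residual degrees of freedom. Every gene named above lost its call without either vehicle library, and all but ERCC6, GTF2H5 and STK19 without either illudin S library. The values held, with ERCC8 at −2.72 to −2.63, ERCC6 at −2.10 to −1.97 and GTF2H5 at −2.42 to −2.32 without any 1 library. For transcription-coupled repair Fisher's exact test gave adjusted p = 0.000998 and for excision repair 0.00892, with 5 lower genes adjusted over the list alone in each list and 1 transcription-coupled repair gene higher.

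Aflatoxin B1, a mould toxin that forms bulky guanine adducts once activated, was run in screen 6. Of 18 translesion synthesis genes 7 were lower and 6 higher (Fisher's exact test, adjusted p = 0.676 and 0.520), the former including MAD2L2 (−1.84 ± 0.25), REV1 (−1.05 ± 0.34) and REV3L, the catalytic subunit of polymerase zeta (−0.68 ± 0.23), and the latter POLH (0.46 ± 0.07). Under the intron-guide scaling 8 were lower and 4 higher. Transcription-coupled repair genes fell in 4 of 6 cases, with ERCC6 at −1.20 ± 0.30, ERCC8 at −1.17 ± 0.27 and UVSSA at −0.69 ± 0.11. In excision repair 6 of 17 were lower and 2 higher, with XPA at −0.93 ± 0.31, and XPC was not called (−0.02 ± 0.02). The helicase genes DDX11 (−1.39 ± 0.15) and BLM (−1.26 ± 0.33), RFWD3 (−1.19 ± 0.25) and RTEL1 (−0.58 ± 0.12) fell, and 9 of 15 RecQ helicase and joint-molecule genes were lower and 2 higher. Of the Fanconi anemia genes 14 of 23 fell, with small values such as −0.31 ± 0.04 for FANCA and −0.28 ± 0.07 for FANCD2. Checkpoint genes of the ATR branch were lower in 8 of 13 cases and higher in 2, with ATR at −0.59 ± 0.24. The deubiquitinase gene BAP1 (0.35 ± 0.07), CHEK2 (0.33 ± 0.06) and SMARCAL1 (0.29 ± 0.06) rose.

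Of all genes 89 were lower and 63 higher under aflatoxin B1 (110 and 17 under the intron-guide scaling, where POLH, BAP1, CHEK2 and SMARCAL1 stayed higher). The count of 152 became 67 and 76 without aflatoxin B1 replicates 1 and 2, and FANCD2 lost its call without either of these (−0.29 and −0.27) or without vehicle replicate 3 (−0.27). Fisher's exact test gave adjusted p = 0.00265 for Fanconi anemia, 0.0406 for the RecQ list and 0.0537 for the ATR-CHK1 checkpoint, with 14, 9 and 8 lower genes adjusted over the list alone.

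BRACO-19, a ligand of G-quadruplex DNA, was the other agent of screen 6. Its lowest value was that of BAP1 (−0.88 ± 0.18), which was higher under aflatoxin B1 in the same screen. Also low were the recombination genes XRCC3 (−0.63 ± 0.20), RAD51B (−0.58 ± 0.13), RAD51D (−0.58 ± 0.08) and XRCC2 (−0.54 ± 0.09), so that 11 of 26 recombination genes fell. End-joining genes fell in 4 of 10 cases, namely NHEJ1 (−0.52 ± 0.14), XRCC4 (−0.49 ± 0.14), LIG4 (−0.40 ± 0.07) and PRKDC (−0.38 ± 0.12), and break ubiquitin signalling in 5 of 9, such as RNF168 (−0.41 ± 0.15). ZNF451, a SUMO ligase acting on trapped TOP2, fell by 0.37 ± 0.12. The kinase gene PKMYT1 (0.40 ± 0.12), ALKBH8 (0.33 ± 0.06) and RIF1 (0.26 ± 0.08) rose. Genes named beforehand for their helicase or chromatin roles at such structures were not called: ATRX (−0.07 ± 0.03), BLM (−0.05 ± 0.06), WRN (0.05 ± 0.04), RTEL1 (0.09 ± 0.04), FANCD2 (−0.03 ± 0.04), BRCA2 (−0.19 ± 0.05) and TOP2A (0.33 ± 0.24).

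Under BRACO-19 36 genes were lower and 24 higher (35 and 20 under the intron-guide scaling). Without BRACO-19 replicate 1 the count of 60 became 30. The lists had, by Fisher's exact test, adjusted p = 0.000147 for homologous recombination, 0.0108 for break ubiquitin signalling and 0.116 for end joining, with 11, 6 and 4 lower genes adjusted over the list alone. Aflatoxin B1 and BRACO-19 were not tested against each other.

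Topotecan, which traps topoisomerase 1 on DNA, was run at 2 dose levels in screen 9. At dose 2 guides against its target TOP1 rose (1.04 ± 0.14), as did BRIP1 (0.73 ± 0.05, 6 of 6 guides), PARG, which removes poly(ADP-ribose) (0.56 ± 0.10), LIG1 (0.53 ± 0.09) and CLSPN (0.44 ± 0.04). DDX11 (−3.06 ± 0.44) fell most, then ATM (−2.08 ± 0.31), POLE3 (−1.90 ± 0.14), SMARCAL1 (−1.83 ± 0.21), RAD51B (−1.80 ± 0.53) and XRCC3 (−1.75 ± 0.43). Of 26 recombination genes 24 fell, also BRCA1 (−1.18 ± 0.10) and RAD51D (−1.17 ± 0.30). Of 9 break ubiquitin signalling genes 7 fell, such as BABAM2 (−1.61 ± 0.36) and ABRAXAS1 (−1.59 ± 0.37), subunits of the BRCA1-A complex. Base excision and single-strand break repair genes were lower in 4 of 23 cases, such as PARP1 (−1.36 ± 0.21) and XRCC1 (−0.83 ± 0.27), and higher in 14, and 6 were lower and 2 higher under the intron-guide scaling. Of the 7 topoisomerase and DNA-protein crosslink repair genes 1 fell, TDP1 (−0.69 ± 0.19), and 4 rose, TOP1 among these, and 1 was lower and 1 higher under the intron-guide scaling. Of the Fanconi anemia genes 18 of 23 fell, with FANCA at −0.79 ± 0.06, while BRIP1 and FAN1 rose. The higher call of FAN1 ended under the intron-guide scaling. ATR was not called (−0.18 ± 0.21).

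At dose 2 of topotecan 101 genes were lower and 131 higher, and 133 and 20 under the intron-guide scaling, where TOP1, BRIP1, PARG, LIG1 and CLSPN stayed higher. At dose 1 40 were lower and 18 higher (81 and 1), and the count of 58 became 38 without dose 1 replicate 1. Dose 2 was lower than dose 1 in 73 genes and higher in 39 (86 and 13 under the intron-guide scaling, 77 and 23 under median-of-ratios scaling), with DDX11 (−1.85 ± 0.31), POLE3 (−1.41 ± 0.12), PARP1 (−1.01 ± 0.17), TOP1 (0.74 ± 0.10) and BRIP1 (0.48 ± 0.05) among them. By Fisher's exact test the lists at dose 2 had adjusted p = 6.57e-11 for homologous recombination, 1.09e-05 for Fanconi anemia and 0.0329 for break ubiquitin signalling among lower calls (25, 19 and 7 adjusted over the list alone). Of 17 excision repair genes 13 were called higher (adjusted p = 0.0103, 13 adjusted over the list alone), but 0 were under the intron-guide scaling, with a list mean of 0.19 and then 0.02.

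Etoposide, which traps topoisomerase 2, changed few genes, and these belonged mostly to end joining. XRCC4 (−1.05 ± 0.29), NHEJ1 (−0.93 ± 0.23), LIG4 (−0.81 ± 0.18) and PRKDC (−0.78 ± 0.10), 4 of the 10 end-joining genes, fell, and so did ZNF451 (−0.72 ± 0.13). ATM (−0.39 ± 0.08, adjusted p = 0.097) was not called, nor were the topoisomerase genes TOP2A (−0.05 ± 0.29) and TOP2B (0.01 ± 0.06) or TDP2 (−0.05 ± 0.07), which frees DNA ends from TOP2. In all 5 genes fell and 2 rose, and 14 and 1 under the intron-guide scaling. With vehicle replicates 5 and 6 alone as the control the count of 7 became 13. One of the higher genes, FAN1, lost its call without either etoposide library and under the intron-guide scaling. End joining had, by Fisher's exact test, adjusted p = 4.16e-05, with 4 genes adjusted over the list alone.

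Bleomycin, which cuts DNA strands directly, gave the broadest loss of end-joining mutants. At dose 2 PRKDC (−1.60 ± 0.21), NHEJ1 (−1.44 ± 0.21), LIG4 (−1.28 ± 0.14), XRCC4 (−1.23 ± 0.27) and DCLRE1C (−1.02 ± 0.17), which opens hairpin ends, fell, 9 of the 10 end-joining genes in all. All 7 genes of the 53BP1-shieldin list fell, with SHLD1 at −1.31 ± 0.21, TP53BP1 at −1.20 ± 0.05, PAXIP1 at −1.12 ± 0.22 and SHLD3 at −0.79 ± 0.24. ATM (−1.18 ± 0.13), TDP1 (−0.99 ± 0.14), which clears damaged ends, the cohesin gene STAG2 (−0.93 ± 0.10), BAP1 (−0.93 ± 0.11) and APEX1 (−0.51 ± 0.09) fell. Fanconi anemia genes were lower in 1 case and higher in 4 of 23, and recombination genes lower in 5 and higher in 4 of 26. The highest values were those of RNASEH2A (1.16 ± 0.05), TOP3A (0.96 ± 0.10), YRDC (0.96 ± 0.16), FEN1 (0.88 ± 0.21) and USP1 (0.84 ± 0.10). Of the 89 genes higher, 52 (58.4%) were among the genes that dropped out under vehicle in at least 6 screens, which make up 141 of 362.

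At dose 2 of bleomycin 79 genes were lower and 89 higher (59 and 93 under the intron-guide scaling), and at dose 1 49 and 51 (50 and 43). Dose 1 gave NHEJ1 at −2.12 ± 0.30 and PRKDC at −1.45 ± 0.31. The higher dose did not simply deepen these: 22 genes were lower and 20 higher at dose 2 than at dose 1, with NHEJ1 (0.68 ± 0.13) higher and PAXX, another end-joining factor (−0.38 ± 0.10), lower. Under the intron-guide scaling that split was 5 and 22, and it was 1 and 1 where 2 guides had to pass the guide test as well. The count of 42 became 16 and 25 without dose 1 replicates 1 and 2, and 15 without dose 2 replicate 2. Fisher's exact test at dose 2 gave adjusted p = 0.000161 for end joining, 0.000456 for 53BP1-shieldin and 0.0537 for break ubiquitin signalling (6 of 9 lower), with 9, 7 and 6 lower genes adjusted over the list alone. Under the intron-guide scaling 9 end-joining and 5 53BP1-shieldin genes were lower.

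Dactinomycin, an antibiotic that intercalates into DNA and blocks transcription, was run at 2 dose levels in screen 9. At dose 2 BTAF1, a regulator of the TATA-binding protein (1.01 ± 0.16), the elongin gene ELOC (0.97 ± 0.11), FEN1 (0.95 ± 0.11), CUL3 (0.86 ± 0.13) and MRE11, a nuclease at breaks (0.66 ± 0.21), rose. TOP1 (−1.55 ± 0.13) fell most, which under topotecan had risen. STAG2 (−1.05 ± 0.13), PAXIP1 (−0.96 ± 0.20), CUL4B (−0.72 ± 0.10), the endonuclease gene APEX2 (−0.71 ± 0.09), USP7 (−0.61 ± 0.08) and BAP1 (−0.60 ± 0.09) fell. End-joining genes fell in 7 of 10 cases, with PRKDC at −0.74 ± 0.08, NHEJ1 at −0.65 ± 0.10 and LIG4 at −0.48 ± 0.06. Fanconi anemia genes were lower in 11 and higher in 3 of 23, such as FANCD2 (−0.36 ± 0.09). TOP2A (−0.07 ± 0.43), TDP2 (0.18 ± 0.13) and XPA (0.05 ± 0.09) were not called. Of the 85 genes higher, 47 (55.3%) were among those that dropped out under vehicle.

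At dose 2 of dactinomycin 69 genes were lower and 85 higher, and 40 and 116 under the intron-guide scaling, where 5 end-joining genes and 6 Fanconi anemia genes were lower and 5 of the latter higher, which takes the mean of the Fanconi list from −0.09 to −0.002. At dose 1 8 were lower and 5 higher (8 and 3 under the intron-guide scaling), with TOP1 at −0.73 ± 0.12, and XRCC4 at −0.60 ± 0.19. That count of 13 became 5 without dose 1 replicate 2, 32 with vehicle replicates 3 and 4 alone and 8 with vehicle replicates 5 and 6 alone. Dose 2 was lower than dose 1 in 43 genes and higher in 50 (18 and 87), with STAG2 (−1.01 ± 0.14), TOP1 (−0.81 ± 0.13) and ELOC (1.09 ± 0.15) among them. That count of 93 became 57 and 43 without dose 1 replicates 1 and 2, and 46 without dose 2 replicate 2. Fisher's exact test at dose 2 gave adjusted p = 0.00885 for end joining and 0.0164 for Fanconi anemia among lower calls, with 7 and 11 adjusted over the list alone.

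**Figure D3:**
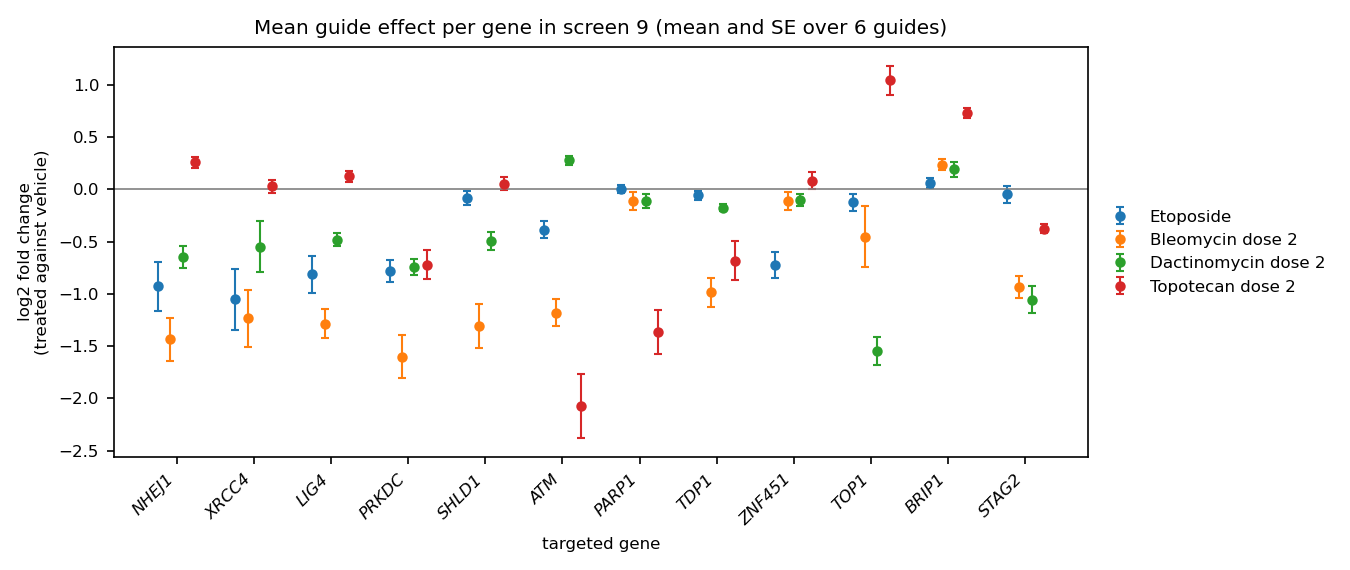
Mean guide log2 fold change against vehicle (y axis) for 12 genes (x axis) under etoposide and the higher doses of bleomycin, dactinomycin and topotecan in screen 9, where points are means and bars the SE over 6 guides. TOP1 lay at 1.04 under topotecan and −1.55 under dactinomycin, and LIG4 fell by 0.81 under etoposide and by 1.28 under bleomycin.

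Over the 15 agents at their highest dose, HMGB2 was higher in 12 and CHEK2 in 10, but only in 2 and 6 under the intron-guide scaling. DDX11 was lower in 14 (not called under etoposide) and FANCI, MCM8, MCM9, PRKDC and RAD51B in 12, against 13, 12, 11, 10, 13 and 11 under that scaling. Some lists had no adjusted p under 0.05 under any agent, by the same exact test. Translesion synthesis genes were lower in 9 and higher in 4 of 18 cases under mitomycin C and lower in 8 and higher in 2 under KL50. Of the 7 topoisomerase and DNA-protein crosslink repair genes 3 were lower under dactinomycin, and 1 was lower and 4 were higher under topotecan. Of the 4 ATM-CHK2 checkpoint genes 2 were lower and 2 higher under SJG-136, and of the 16 replication core genes 6 were higher under topotecan, such as LIG1, and 4 lower under TMZ. The ATR-CHK1 list came closest under aflatoxin B1. These genes were counted after their values were seen, apart from where they are named above. Across genes, which are not independent replicates, profiles of agents from different screens had a median r of 0.28 over 91 pairs, from −0.08 to 0.92. The highest were chlorambucil and mitomycin C (r = 0.92, rho = 0.73), TMZ and MMS (r = 0.91, rho = 0.71), MTZ and chlorambucil (r = 0.90, rho = 0.71), and mitomycin C and cisplatin (r = 0.88, rho = 0.75). No p is given for these, since genes are not replicates.

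**Figure D4:**
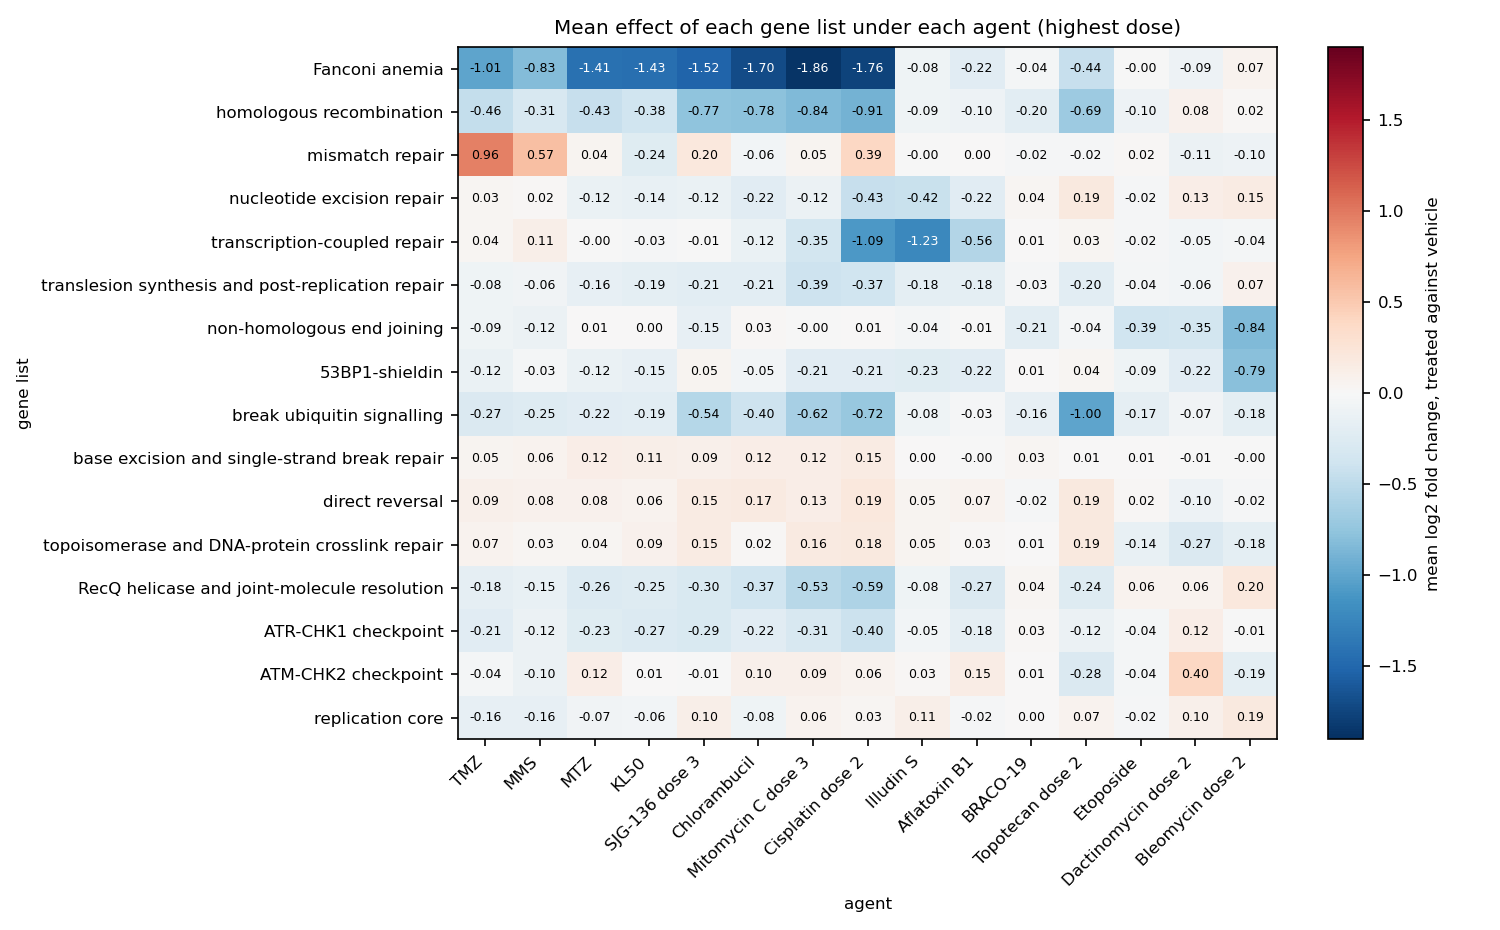
Mean log2 fold change against vehicle (colour and printed value) of the genes of each of 16 lists (y axis) under each of 15 agents at the highest dose (x axis). The Fanconi anemia list ran from −1.86 under mitomycin C to 0.07 under bleomycin, mismatch repair reached 0.96 under TMZ, and end joining −0.84 under bleomycin, while the means above 0 of base excision under KL50, direct reversal under chlorambucil and excision repair under topotecan fell to about 0 under the intron-guide scaling.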

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

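Every choice below except the intron-guide scaling, which was added after the table was seen, was made before the data were examined. Scaling on non-targeting guides was planned and not run, since the table holds none, and the run with no filter equals the main one because the filter removed 0 guides. Alternatives run in all screens gave 40 counts of called genes each, vehicle pairs in screens 6 and 9 gave 10 or 8, and a count is printed here where it moved by over 1.5 times. Where a cause is not stated, the cause was not tested. Names ending in a screen number stand for vehicle against the start. Of the 886 named gene results, 8 changed direction under some setting, and 288 called ones lost their call without some library.

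With the intron-guide scaling 760 named results stayed the same, 112 lost their call, 7 gained one and 7 changed sign. The sign changes were NHEJ1 under MTZ (−0.0639), ALKBH2 under chlorambucil (−0.00892), ALKBH1 (−0.0383) and SHLD2 (−0.0560) under mitomycin C dose 3, and ERCC8 (−0.0753), MGMT (−0.00493) and MSH3 (−0.000738) under topotecan dose 2, all small higher values that moved down with the scaling by construction. Counts became 15 (etoposide), 153 (topotecan dose 2) and 27 (bleomycin dose 2 against dose 1). Median-of-ratios scaling moved no count and ended 15 named calls.

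H2AX under aflatoxin B1 turned to 0.0679 with vehicle replicates 3 and 4 alone, 0.0398 without vehicle replicate 1 and 0.0231 without aflatoxin B1 replicate 1, and without other libraries it ranged down to −0.0486. With vehicle replicates 3 and 4 alone the count became 32 (dactinomycin dose 1), and with replicates 5 and 6 alone 8 (dactinomycin dose 1) and 13 (etoposide). Replicates 1 and 2 alone moved none.

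All screens in 1 fit raised 11 counts, to 2 (SJG-136 dose 1), 64 (SJG-136 dose 2), 28 (illudin S), 133 (cisplatin dose 1), 257 (cisplatin dose 2) and 44 (dactinomycin dose 1). It also gave 11 (etoposide), 91 (topotecan dose 1), 181 (cisplatin dose 2 against dose 1), 87 (bleomycin dose 2 against dose 1) and 8 (KL50 against MTZ). DESeq2 on counts summed per gene raised 17, to 170 (MTZ), 200 (TMZ), 111 (KL50 against TMZ), 110 (MTZ against TMZ), 21 (KL50 against MTZ) and 2 (SJG-136 dose 1). Also raised were 60 (SJG-136 dose 2), 265 (chlorambucil), 77 (illudin S), 103 (BRACO-19), 136 (mitomycin C dose 2) and 228 (mitomycin C dose 3 against dose 2). The others were 140 (cisplatin dose 1), 262 (cisplatin dose 2), 180 (cisplatin dose 2 against dose 1), 33 (dactinomycin dose 1) and 11 (etoposide). The edgeR test on summed counts raised 7, to 11 (KL50 against MTZ), 3 (SJG-136 dose 1), 65 (SJG-136 dose 2), 29 (illudin S), 109 (cisplatin dose 1), 130 (cisplatin dose 2 against dose 1) and 27 (dactinomycin dose 1).

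Asking for 2 guides past the guide test as well lowered 20 counts, to 60 (KL50), 53 (MTZ), 73 (TMZ), 40 (KL50 against TMZ), 42 (MTZ against TMZ), 12 (SJG-136 dose 2) and 72 (aflatoxin B1). That rule left 28 (BRACO-19), 48 (mitomycin C dose 2), 78 (mitomycin C dose 3 against dose 2), 46 (bleomycin dose 1), 98 (bleomycin dose 2), 4 (dactinomycin dose 1) and 77 (dactinomycin dose 2). It kept 56 (MMS), 20 (topotecan dose 1), 138 (topotecan dose 2), 57 (topotecan dose 2 against dose 1), 18 (dactinomycin dose 2 against dose 1) and 2 (bleomycin dose 2 against dose 1). Fits of only the 2 groups compared, with fewer residual degrees of freedom by construction, lowered 23, to 14 (KL50), 10 (MTZ), 37 (TMZ), 5 (KL50 against TMZ), 2 (MTZ against TMZ), 1 (KL50 against MTZ), 0 (SJG-136 dose 2) and 44 (SJG-136 dose 3). Such fits left 35 (SJG-136 dose 3 against dose 1), 55 (chlorambucil), 0 (illudin S), 28 (BRACO-19), 31 (mitomycin C dose 2), 107 (mitomycin C dose 3), 11 (mitomycin C dose 3 against dose 2) and 2 (cisplatin dose 1). The last were 0 (screen 8), 2 (cisplatin dose 2 against dose 1), 7 (dactinomycin dose 1), 38 (topotecan dose 1), 1 (topotecan dose 2 against dose 1), 0 (dactinomycin dose 2 against dose 1) and 0 (bleomycin dose 2 against dose 1).

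Rank aggregation moved 34 counts, 31 of them down, to 51 (KL50), 50 (MTZ), 59 (TMZ), 78 (screen 2), 42 (MTZ against TMZ), 6 (KL50 against MTZ), 1 (SJG-136 dose 1), 63 (SJG-136 dose 3) and 46 (screen 3). Others became 62 (SJG-136 dose 3 against dose 1), 60 (chlorambucil), 74 (screen 4), 53 (screen 5), 55 (aflatoxin B1), 37 (BRACO-19), 60 (screen 6), 47 (mitomycin C dose 2) and 88 (mitomycin C dose 3). Further counts were 59 (screen 7), 54 (mitomycin C dose 3 against dose 2), 80 (cisplatin dose 2), 53 (screen 8), 40 (bleomycin dose 1), 46 (bleomycin dose 2), 6 (dactinomycin dose 1), 44 (dactinomycin dose 2) and 46 (MMS). The rest were 27 (topotecan dose 1), 74 (topotecan dose 2), 62 (screen 9), 46 (topotecan dose 2 against dose 1), 16 (dactinomycin dose 2 against dose 1), 0 (bleomycin dose 2 against dose 1) and 3 (Time1 against Time0).

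With the replicate number as a block (replicate block) 11 counts moved, 10 of them down, to 5 (KL50 against MTZ), 21 (SJG-136 dose 2), 58 (chlorambucil), 0 (illudin S), 71 (aflatoxin B1), 26 (BRACO-19), 54 (mitomycin C dose 2), 1 (cisplatin dose 1), 29 (screen 8), 0 (cisplatin dose 2 against dose 1) and 7 (dactinomycin dose 1). Pairing was checked by correlating the differences between replicates of 2 groups across guides: r lay between −0.15 and 0.10. Thus no deviation shared by the same numbers was seen, which cannot show whether same-numbered samples were handled together. The replicate block ended 171 named calls and changed no direction.

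Leaving out each library in turn moved counts by over 1.5 times in 56 of 200 cases, 55 of them down, where a lone sample is assumed to vary like the other groups. The lowest and highest counts were 74 to 90 (KL50), 59 to 81 (MTZ), 90 to 114 (TMZ), 247 to 278 (screen 2), 32 to 46 (KL50 against TMZ), 0 to 5 (KL50 against MTZ), 32 to 42 (MTZ against TMZ) and 0 (SJG-136 dose 1). They were 4 to 18 (SJG-136 dose 2), 104 to 119 (SJG-136 dose 3), 235 to 244 (screen 3), 97 to 116 (SJG-136 dose 3 against dose 1), 148 to 191 (screen 4), 52 to 63 (chlorambucil), 0 to 3 (illudin S) and 186 to 201 (screen 5). Ranges were 67 to 137 (aflatoxin B1), 30 to 57 (BRACO-19), 294 to 318 (screen 6), 244 to 259 (screen 7), 32 to 39 (mitomycin C dose 2), 158 to 181 (mitomycin C dose 3), 80 to 97 (mitomycin C dose 3 against dose 2) and 0 to 2 (cisplatin dose 1). Next came 40 to 75 (cisplatin dose 2), 0 (screen 8), 1 to 6 (cisplatin dose 2 against dose 1), 5 to 14 (dactinomycin dose 1), 43 to 69 (dactinomycin dose 2 against dose 1), 105 to 158 (dactinomycin dose 2), 0 (Time1 against Time0) and 72 to 107 (bleomycin dose 1). The last were 15 to 32 (bleomycin dose 2 against dose 1), 119 to 160 (bleomycin dose 2), 5 to 8 (etoposide), 81 to 121 (MMS), 38 to 61 (topotecan dose 1), 185 to 235 (topotecan dose 2), 288 to 306 (screen 9) and 77 to 95 (topotecan dose 2 against dose 1).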

Other observations

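Both tests on BRIP1 below were chosen only after the result was seen. The others were written before their own values were computed, but for a pattern already seen in the calls.

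PRKDC, the kinase subunit of end joining, fell under agents as different as TMZ (−0.66) and bleomycin (−1.60). It was called lower under 12 of 15 agents, and NHEJ1, XRCC4 and LIG4 under 4 each, a difference in calls that was not tested. DDX11, a helicase tied to sister chromatid cohesion, was lower under 14 of 15 agents, with −3.06 under topotecan and −2.77 under mitomycin C, although it is not a member of the Fanconi anemia list. STAG2, a subunit of cohesin, was lower under 6 of 15 agents, with −0.93 under bleomycin and −1.05 under dactinomycin.

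Genes that drop out in vehicle made up 58.4% of the higher calls under bleomycin dose 2 and 55.3% under dactinomycin dose 2, against 141 of all 362 genes. The share was also above that of all genes under BRACO-19 (58.3%), etoposide (50% of 2 calls), cisplatin dose 1 (45.5%), SJG-136 dose 2 (42.9%) and bleomycin dose 1 (41.2%), where the cause was not tested. For bleomycin and dactinomycin 1 technical explanation is fewer cell doublings under the drug. Across genes, Spearman's rho between the drug effect and the mean effect of vehicle against the start in the 7 other screens was −0.37 for bleomycin, which fits fewer doublings but does not show that they account for each rise. It was −0.23 for dactinomycin, between the bounds set, so that the explanation stays open there. At dose 1 of these drugs rho was −0.04 for bleomycin and 0.22 for dactinomycin, and elsewhere it was −0.13 for BRACO-19 and −0.23 for cisplatin dose 1. Chance values common to the 6 shared vehicle libraries would also enter MMS and etoposide, set against the same libraries. The lower rho of these was 0.22, which argues against such values as the source of the negative rho of bleomycin. It cannot speak to differences among the vehicle libraries or to the 2 bleomycin libraries, since rho was not computed with vehicle pairs alone.

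BRIP1 was higher under topotecan dose 2 (0.73), and less so under bleomycin dose 2 (0.24) and dactinomycin dose 2 (0.19), and lower under crosslinking agents such as mitomycin C. A single deviating guide is excluded under topotecan, since 6 of 6 guides were higher. Fewer doublings under topotecan cannot account for the whole rise, since they can move a gene by no more than its vehicle effect. For BRIP1 that effect was 0.0070 (mean over the 7 other screens, SD 0.061). Under the intron-guide scaling it was −0.36 (SD 0.068) and the rise was 0.56, so that fewer doublings could make up part of the rise there. No biological explanation was tested.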
